A study of Mus musculus and Homo sapiens with 6 samples.

How the data were processed

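The series holds 6 samples sequenced on the Ion Torrent Proton: 4 libraries of mouse liver RNA (untreated, APAP, APAP plus exosomes, APAP plus G-CSF), 1 small RNA library of APAP plus exosome liver and 1 small RNA library of exosomes from pooled human serum. Each liver RNA library was a pool of 3 livers per the labels. Samples were grouped by their treatment labels, which gave 1 library per group.

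The authors deposited a gene table in RPM, reads scaled to library size, 43280 entries with 1 column for each liver library. The submitters' processing notes give the mouse build mm10, and aligner, counting rule and gene annotation are not given in the sources used here. The deposited transcript table holds a score for each of 93948 transcripts and 36022 gene models, whose unit is not given in the sources used here, and the column totals differ between libraries. The small RNA tables hold a read count per microRNA hairpin and strand, per the file headers.

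Whole reads were recovered from the RPM by dividing by the value of 1 read: 100% of values lay within 0.05 reads of a whole number in each library. This gave 10909840, 9469758, 7787220 and 13895838 assigned reads for untreated, APAP, APAP plus exosomes and APAP plus G-CSF, so that 1 read stands for 0.0917, 0.106, 0.128 and 0.0720 RPM. Genes with at least 1 read numbered 21926, 21941, 21311 and 22437, and genes with at least 10 RPM 7590, 8273, 6823 and 8316.

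For each of the 6 comparisons the log2 ratio of RPM was taken with 1 RPM added to both sides, for genes with at least 10 RPM in either library, and a gene counted as higher or lower from 2-fold. Fold values in the text are ratios of RPM without the added 1 RPM, with the 95% Clopper-Pearson interval of the ratio of rates. Where a library had 0 reads, the fold is a lower limit that sets the absent level to 3 reads. With 1 library per group no test between conditions was possible. An exact binomial test with adjusted p below 0.05, chosen after the data were seen, compares libraries and not conditions. Of 42 gene lists 39 had the 5 measured members needed for a test. A member was measured if it reached 10 RPM in at least 1 of the 4 liver libraries. Some measured members thus lay below 10 RPM in both libraries of a comparison. The median log2 ratio of a list was placed among 10000 random lists matched on expression in 20 bins from 9264 genes, and a list stood apart below percentile 2.5 or above 97.5. The gene lists, groups, comparisons and alternatives, other than the ones added after seeing the data, were fixed before the data were examined; which lists the text describes was chosen after list results were seen.

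Genes named in the text are the 10 highest and 10 lowest of each comparison, up to 4 members of each described list with the largest ratios, and Dpp4 and Csf3r in all 4 libraries. The 27 entries whose name is a date were left out of naming, and the 4 entries under 2 names given more than once were left out of all tests. Gene coordinates are those of GRCm38.p6.

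Genes shifted by APAP are those at least 2-fold from untreated liver, among genes with at least 10 RPM in either the untreated or the APAP library. The log2 level with exosomes or G-CSF was called nearer to the closer of the untreated and APAP levels, with exact binomial intervals of the share and 100 simulated draws of an unchanged library. Overlaps of gene sets that share a library were compared with the product of set sizes over genes tested and with 100 simulated draws. For small RNA, reads on both strands were summed per hairpin and given as percent of all hairpin reads with exact binomial intervals.

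The steps were tested on simulated data. Planted 3-fold changes were recovered in 98% to 99% of cases and 6-fold changes in 99% to 100%, with 0 false calls by the fold rule in each comparison, and 95.2% to 95.7% of intervals held the true ratio. The exact binomial test made 2 to 7 false calls per comparison. These simulated libraries held counting error only and no spread between animals or pools, so the rates do not hold for differences between real pools. The list test was checked for APAP against untreated only. There 7 of 200 null lists stood apart (3.5%), and 20 of 20 planted lists, with every member set 2-fold higher, were found. The null lists were drawn at random from the same genes as the reference lists, so a low rate follows from the setup. It does not hold for lists of genes that change together, nor for differences between real pools. The transcript scores summed per gene had a Spearman coefficient with the gene table, across genes, of 0.72, 0.69, 0.72 and 0.73 in the order untreated, APAP, exosomes and G-CSF.

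Alternatives covered the added RPM (0.1 and 5), the filter on low values (none and 50 RPM), the fold (1.5 and 4), scaling (median of ratios, trimmed mean of log ratios, the 50 most abundant genes left out), named genes only, counting intervals that exclude 1, the transcript table, and for small RNA the summing of copies and the most abundant hairpin left out. An exact binomial test, the sex lists left out and forward strand reads only were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not used here, no values of single people were analysed, and the mouse and human small RNA libraries were not tested against each other.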

Results

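The series measured RNA in the livers of C57BL/6 mice, a common inbred strain, after acetaminophen (APAP), a painkiller whose overdose injures hepatocytes around the central vein. Each of the 4 liver RNA libraries was made from a pool of 3 livers and stood for 1 condition. The conditions were untreated mice, mice given APAP at 500 mg/kg, mice given the same dose of APAP and exosomes from 1 ml of serum, and mice given the same dose of APAP and 100 µg/kg of G-CSF, the growth factor that drives neutrophil production. A small RNA library of APAP plus exosome liver and a small RNA library of exosomes from human serum completed the 6 samples. The gene table held 10909840 assigned reads for the untreated library, 9469758 for APAP, 7787220 for APAP plus exosomes and 13895838 for APAP plus G-CSF. With 1 library per condition there was no replicate check of any difference, so levels are described as higher or lower and no p-value across genes is given. Intervals in parentheses are 95% intervals of a ratio from the read counts. They and the lower limits of ratios against 0 reads cover counting error only. A percentile of a gene list among 10000 random lists matched on expression describes these libraries and not the conditions. The time between dosing and collection is not given in the sources used here.

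Sex-linked transcripts separated the APAP library from the other 3. Xist, the noncoding RNA that silences one X chromosome in female cells (chromosome X, 103460373 to 103483233), stood at 437 RPM in untreated liver, 0.528 with APAP, 218 with APAP plus exosomes and 398 with APAP plus G-CSF. The Y-linked RNA helicase gene Ddx3y (chromosome Y, 1260715 to 1286628) stood at 0.183, 48.5, 3.08 and 0 RPM in the same order, where 0 reads in the G-CSF library allow up to 0.216 RPM. Of the 28 liver genes listed for sex-biased expression, 26 lay on the male side in the APAP library against each of the other 3, among them Mup20, a male-biased urinary protein gene, at 883 RPM against 39, 17.7 and 16.3. Each difference from the APAP library below therefore goes together with a sex-linked difference. Structural RNA and a few abundant transcripts also differed in share: Yam1 took 5.50% of untreated reads, 7.89% with APAP, 13.2% with exosomes and 1.79% with G-CSF, and the mitochondrial ribosomal RNAs 2.40%, 3.02%, 5.77% and 1.94%. The 50 most abundant genes took 36.9%, 39.6%, 46.5% and 32.4% of the reads. Yam1 was singled out after its values were seen. Values of near-identical gene copies (Saa1 and Saa2, Hspa1a and Hspa1b, Gsta1 and Gsta2, and the Cyp2b, Sult2a, Mup and haemoglobin genes) are uncertain, since how reads shared by copies were counted is not given in the sources used here.

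**Figure D1:**
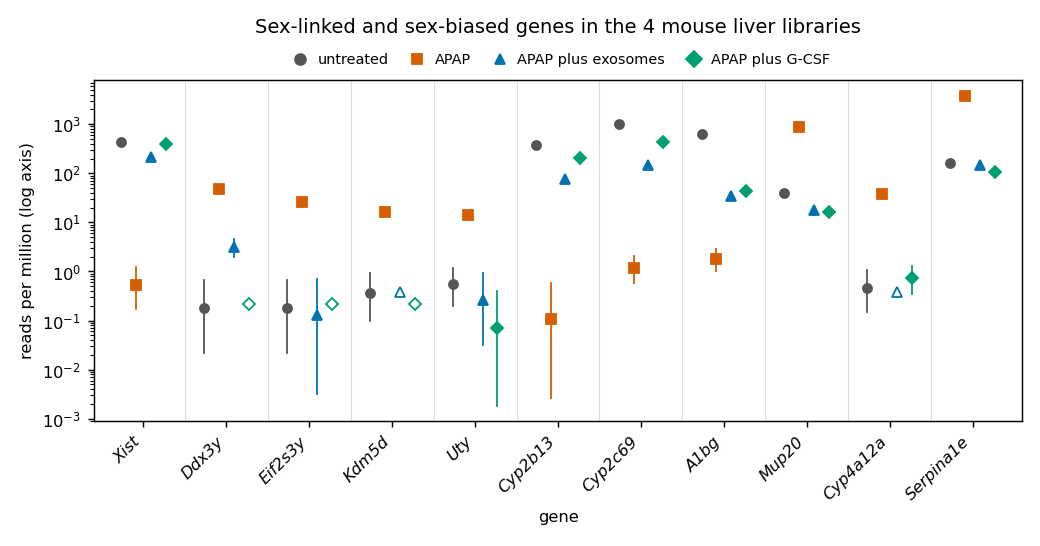
RPM (log axis) of sex-linked and sex-biased genes in the 4 liver libraries, with 95% counting intervals as vertical lines and open markers for 0 reads drawn at the level of 3 reads. The APAP library alone has Xist near 0.528 RPM and Ddx3y at 48.5 RPM, and it parts from the other 3 libraries in the female-biased Cyp2b13 and in the male-biased Mup20.

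The title of the untreated library reads DPP4-minus, Dpp4 being the gene of the peptidase CD26, while its treatment label reads untreated. Whether these mice lacked a working Dpp4 gene is not given in the sources used here, so the baseline of the 3 comparisons with untreated liver may differ from wild type. Dpp4 (chromosome 2, 62330073 to 62412315) was detected in all 4 libraries, at 5.68 RPM in untreated liver, 7.29 with APAP, 3.47 with APAP plus exosomes and 9.57 with APAP plus G-CSF. Dpp4 was 2.76-fold lower (1.81 to 4.34) with exosomes than with G-CSF and 1.64-fold lower (1.03 to 2.68) than in untreated liver. The median gene of the exosome library was itself lower, and relative to it the log2 ratios of Dpp4 were -0.60 and -0.20. Csf3r, the receptor of G-CSF (chromosome 4, 126023441 to 126044975), stood at 2.93, 11.4, 10.5 and 17.8 RPM in the same order, 3.89-fold higher (2.6 to 5.96) with APAP than in untreated liver and 1.56-fold higher (1.24 to 1.97) with G-CSF than with APAP alone.

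The library labelled APAP, without exosomes or G-CSF, was set against untreated liver. Immediate early genes, transcription factors and signalling genes that respond within minutes of stress, stood higher with APAP: 23 of 26 measured members were at least 2-fold higher relative to the median gene and none was 2-fold lower. Jun was 20.04-fold higher (17.4 to 23.3), Maff 26.4-fold (18.4 to 39.1), Gadd45b 25.6-fold (14 to 51.9) and the matrix protein gene Ctgf 17.4-fold (12.1 to 25.7). Lipid synthesis stood lower. It had 20 of 21 lipogenesis genes and 24 of 25 cholesterol synthesis genes at least 2-fold lower and none 2-fold higher. Fasn, the fatty acid synthase gene (chromosome 11, 120805958 to 120825166), was 19.6-fold lower (18.3 to 21), the elongase gene Elovl6 17-fold (13.3 to 22.1), the lipase gene Pnpla3 76.5-fold (20.8 to 636) and the acetyl-CoA synthetase gene Acss2 12.4-fold (10.7 to 14.3). In cholesterol synthesis, Idi1 was 17.6-fold lower (10.1 to 33.5), Mvd 9.08-fold (6.06 to 14.2), Nsdhl 7.49-fold (5.997 to 9.45) and Fdps 7.36-fold (6.29 to 8.65).

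Genes of hepatocytes around the central vein, where APAP is bioactivated, stood lower in 18 of 24 cases. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 68.4-fold lower (41.3 to 123), the glutamate transporter gene Slc1a2 25.6-fold (20.8 to 31.7), Cyp2c37 24.4-fold (21.2 to 28.2) and Glul, the glutamine synthetase gene, 7.05-fold (6.65 to 7.49). Of 26 cytochrome P450 genes 19 were lower and 2 higher. Members of the sex-biased list were among them, such as Cyp2b13 at 3637-fold lower (655 to 144233) and Cyp2b9 at 152-fold (111 to 214). Bile acid genes were lower in 14 of 26 cases and higher in 1, with Akr1d1 16-fold lower (13.4 to 19.2) and the bile salt export pump gene Abcb11 7.61-fold (7.07 to 8.2). Among 30 genes of the urea cycle and amino acid breakdown 16 were lower and none higher, led by the histidine ammonia-lyase gene Hal at 5.82-fold lower (5.43 to 6.24) and the methyltransferase gene Bhmt at 5.47-fold (5.25 to 5.71).

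Inflammatory and stress genes stood higher. Among 17 cytokine and chemokine genes 10 were higher and 2 lower, among them the chemokine genes Cxcl2, 29.95-fold higher (9.88 to 148), and Ccl2, 18.4-fold (8.66 to 46.9), and the TWEAK receptor gene Tnfrsf12a, 17.5-fold (13.8 to 22.6). Neutrophil markers were higher in 7 of 10 measured cases, with Lcn2 at 36.3-fold higher (29.8 to 44.7), S100a8 at 12.7-fold (5.52 to 35.8) and S100a9 at 10.8-fold (5.78 to 22.3). Only these 10 of 32 listed neutrophil genes reached 10 RPM in any liver library, so the filter favours genes high in a treated library. Hepatocytes also make Lcn2. Acute phase genes, which encode plasma proteins made in inflammation, were higher in 9 of 25 cases and lower in 2, with Saa1 (chromosome 7, 46740497 to 46743181) at 12.2-fold higher (10.7 to 14) and Saa2 (chromosome 7, 46751833 to 46754313) at 11.5-fold (9.74 to 13.8). NRF2 targets, the genes of the antioxidant response, were higher in 12 of 26 cases and lower in 2: the cystine transporter gene Slc7a11 was 36.2-fold higher (21.8 to 65.3), the glutathione transferase gene Gsta1 50.2-fold (35.7 to 72.7) and the haem oxygenase gene Hmox1 7.78-fold (6.84 to 8.87). Heat shock genes were higher in 7 of 16 cases, led by the chaperone genes Hspa1a at 179-fold higher (69.7 to 661) and Hspa1b at 33.2-fold (25.5 to 43.9). The p53 targets were higher in 7 of 17, led by the cell cycle inhibitor gene Cdkn1a at 9.82-fold higher (8.12 to 12). Fatty acid oxidation and lipid droplet genes were higher in 13 of 36 cases, including Plin4 at 16.3-fold higher (12.6 to 21.6) and Angptl4 at 9.01-fold (8.1 to 10.05). Interferon response genes were lower in 14 of 28 cases, such as Gbp6 at 6.8-fold lower (5.27 to 8.91), and higher in 2, such as Rsad2 at 4.05-fold higher (3.35 to 4.94).

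Of 8723 genes that reached 10 RPM in either library, 1090 were at least 2-fold higher and 694 at least 2-fold lower with APAP. The median gene of the list background stood at 0.21 on the log2 scale, and the counts of list members are relative to it. Under median-of-ratios scaling the split was 813 higher and 867 lower, and under a trimmed mean of log ratios 667 and 1000, so which direction held more genes depended on the scaling. Among the 39 lists with enough members, 14 had medians above and 9 below the central 95% of random lists, where lists of randomly drawn genes would give 1.95 in all. Genes of a list can change together between pools, so more lists than that may stand apart without an effect of treatment. Bile duct markers were among those above, and lost their place with no filter on low values. Medians relative to the median gene were 2.48 for immediate early genes, 1.24 for cytokines, 1.61 for neutrophil markers, 0.58 for acute phase genes, 0.82 for NRF2 targets, 0.57 for heat shock genes, 0.92 for p53 targets and 0.23 for fatty acid oxidation. They were -2.19 for lipogenesis, -2.19 for cholesterol synthesis, -1.64 for pericentral genes, -2.08 for cytochrome P450 genes, -1.21 for bile acid genes, -1.11 for urea and amino acid genes and -1.05 for interferon genes. All of these lay above or below every random list except neutrophil markers (percentile 99.97), heat shock genes (99.83), p53 targets (99.99) and fatty acid oxidation (99.18). At a minimum of 50 RPM the interferon and fatty acid oxidation lists no longer stood apart, nor did fatty acid oxidation in the transcript table. Of the 20 genes with the most extreme ratios 11 belonged to the sex lists. Among them were the female-biased cytochrome P450 genes Cyp3a41a, 296-fold lower (161 to 618), and Cyp3a16, 263-fold (112 to 811). The count covers listed genes only, so unlisted genes that differ by sex may be among the other extremes. The list of genes that tell male from female mice had 4 of 5 members higher and 1 lower (median 3.48).

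**Figure D2:**
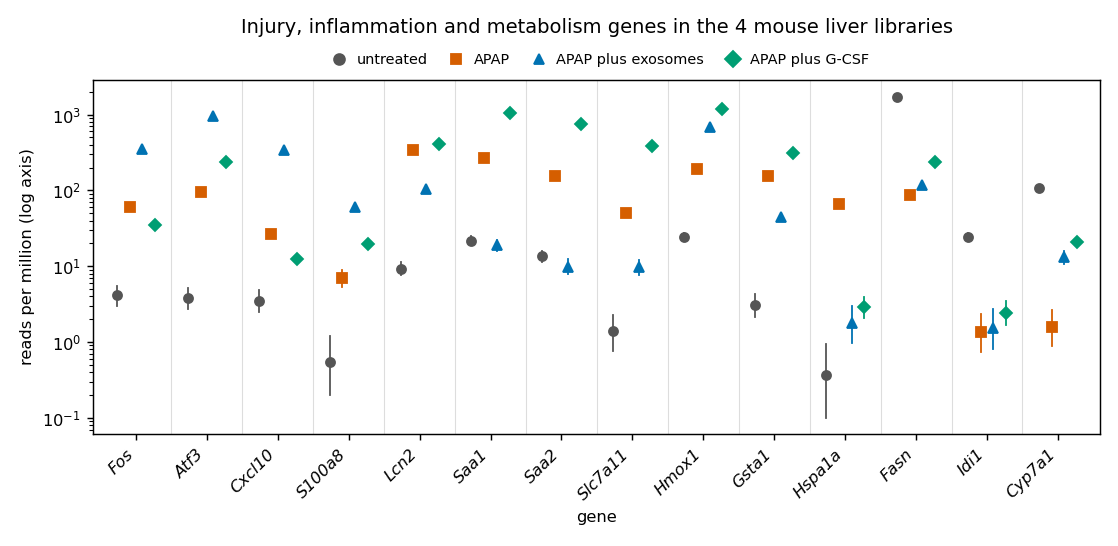
RPM (log axis) of injury, inflammation, antioxidant and lipid synthesis genes in the 4 liver libraries, with 95% counting intervals as vertical lines. Fos and Cxcl10 were highest with APAP plus exosomes (351 and 341 RPM), Saa1 and Slc7a11 were highest with APAP plus G-CSF (1051 and 381 RPM), and Fasn was highest in untreated liver (1722 RPM).

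APAP plus exosomes was set against APAP alone, across the sex-linked difference. Immediate early genes stood higher still with exosomes, 24 of 26 by at least 2-fold relative to the median gene and none lower: the antiproliferative gene Btg2 was 10.9-fold higher (9.82 to 12.1), the matrix protein gene Cyr61 9.28-fold (8.37 to 10.3), the nuclear receptor gene Nr4a1 6.71-fold (5.11 to 8.94) and Maff 6.33-fold (5.84 to 6.87). Of the 17 p53 targets 10 were higher and 1 lower, with the growth arrest gene Gadd45a at 12.8-fold higher (11.4 to 14.5) and the stress cytokine gene Gdf15 at 6.65-fold (5.97 to 7.42). Chemokine and cytokine genes were higher in 10 of 17 cases, led by the neutrophil attractant genes Cxcl2 at 16-fold higher (12.7 to 20.4) and Cxcl1 at 5.72-fold (5.04 to 6.51) and the interferon-inducible Cxcl10 at 12.8-fold (11.2 to 14.6). Interferon response genes were higher in 13 of 28 cases and lower in 0, with Ifit2 at 8.51-fold higher (5.86 to 12.7), Mx2 at 7.4-fold (5.21 to 10.8) and Ifit3 at 7.12-fold (4.96 to 10.5).

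Acute phase genes stood lower with exosomes in 7 of 25 cases and higher in 2. Saa1 was 13.9-fold lower (11.8 to 16.6), Saa2 15.8-fold (12.6 to 20.2), the serum amyloid P gene Apcs 7.2-fold (6.29 to 8.27) and the orosomucoid gene Orm2 5.35-fold (4.13 to 7.01). Hspa1a and Hspa1b, the inducible heat shock genes that stood high with APAP, were 36.6-fold lower (21.6 to 67.3) and 52.8-fold (35.9 to 81.1). The heat shock list as a whole did not stand apart, under the main setting or any of 8 alternatives. Its 17 genes summed to 3688 RPM with APAP and 5002 RPM with exosomes. The DNA replication genes Mcm2 and Mcm10 were 8.99-fold lower (5.29 to 16.4) and 4.17-fold (2.78 to 6.44), while of 11 cell cycle genes 3 were lower and 1 higher. Of 23 genes of hepatocytes around the portal vein 11 were higher and 0 lower, such as Hsd17b6 at 4.49-fold higher (3.99 to 5.07).

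Several blood and immune cell lists stood higher in the exosome library relative to the median gene, but not all did on the deposited scale. There the summed RPM of all listed genes was 2817 with APAP and 1287 with exosomes for monocyte and macrophage markers. It was 417 and 417 for neutrophil markers, 572 and 2133 for red cell and platelet genes, and 836 and 1438 for Kupffer markers. Neutrophil markers were higher in 7 of 10 cases and lower in 1, with the neutrophil granule gene Ngp at 20.6-fold higher (10.9 to 43.6), Retnlg at 19.6-fold (11.5 to 36.5) and S100a8 at 8.64-fold (6.67 to 11.4). Red cell and platelet genes were higher in 6 of 6, with the haemoglobin gene Hbb-bs at 4.74-fold higher (4.54 to 4.95) and 1270.0 RPM against 268. Only these 6 of 20 listed genes reached 10 RPM in any liver library. They include the haemoglobin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2, among them near-identical copies, and the red cell gene Alas2. In every comparison the count and percentile of this list thus rest largely on haemoglobin genes and say little on platelets. Monocyte and macrophage markers were higher in 9 of 17 cases and lower in 2, going both ways: the endotoxin co-receptor gene Cd14 was 5.58-fold higher (4.79 to 6.52) while the fibronectin gene Fn1, which hepatocytes also express, was 3.33-fold lower (3.23 to 3.43) and the galectin gene Lgals3 3.8-fold (2.98 to 4.89). Kupffer cell markers were higher in 3 of 13 cases and lower in 1, where the scavenger receptor gene Marco was 4.24-fold lower (3.38 to 5.36) and Hmox1, which is also an NRF2 target, 3.59-fold higher (3.41 to 3.79). Cytochrome P450 genes were higher in 13 of 26 cases and lower in 2, led by sex-biased members: Cyp2b13 was 722-fold higher (129.6 to 28674) and Cyp2d9 45.4-fold lower (37.9 to 54.8). Yam1 and the mitochondrial ribosomal RNAs took 13.2% and 5.77% of the reads with exosomes, against 7.89% and 3.02% with APAP alone.

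Of 8592 genes 481 were at least 2-fold higher and 2164 at least 2-fold lower with exosomes, and the median gene of the list background stood at -0.53 on the log2 scale. Median-of-ratios scaling gave 997 higher and 888 lower, and a trimmed mean of log ratios 1016 and 819. List medians relative to the median gene were 2.49 for immediate early genes, 1.97 for p53 targets, 1.17 for cytokines, 0.90 for interferon genes, 2.42 for neutrophil markers and 1.07 for monocyte and macrophage markers, each above every random list. Red cell and platelet genes had a median of 1.95 (percentile 99.98), periportal genes 0.87 (99.58), Kupffer markers 0.79 (99.71), cytochrome P450 genes 0.90 (99.95), acute phase genes -0.45 (0.005) and cell cycle genes -0.85 (0.46). In all, 13 of 39 lists stood apart above and 3 below. The cell cycle and monocyte lists lost their place with no filter on low values, the monocyte list also at 50 RPM, and the periportal and Kupffer lists in the transcript table. Of the 20 most extreme genes 15 belonged to the sex lists, with Xist 414-fold higher (177 to 1276). Unlisted genes that differ by sex may be among the rest.

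APAP plus G-CSF was set against APAP alone, again across the sex-linked difference. NRF2 targets stood higher with G-CSF in 7 of 26 cases, relative to the median gene, and lower in 0. Slc7a11 (chromosome 3, 50364936 to 50499087) was 7.64-fold higher (6.96 to 8.42), Hmox1 6.28-fold (5.99 to 6.6), the efflux transporter gene Abcc4 6.07-fold (4.68 to 7.99) and the glutathione transferase gene Gsta2 2.88-fold (2.37 to 3.53). Lipogenesis genes were higher in 8 of 21 cases and lower in 0, with Elovl6 at 4.84-fold higher (3.75 to 6.34), the desaturase gene Scd1 at 3.3-fold (3.22 to 3.39) and Thrsp at 3.22-fold (2.74 to 3.8). Pericentral genes were higher in 9 of 24 cases and lower in 1: Cyp2c37 was 19.5-fold higher (17 to 22.6), Cyp7a1 13.2-fold (7.86 to 23.8), Slc1a2 7.23-fold (5.85 to 9.03) and Glul 3.65-fold (3.43 to 3.88). Neutrophil markers were higher in 3 of 10 cases, with the chemokine receptor gene Cxcr2 at 3.16-fold higher (2.09 to 4.95), S100a8 at 2.84-fold (2.16 to 3.77) and S100a9 at 2.39-fold (1.91 to 3.003).

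Red cell and platelet genes were lower in 3 of 6 cases, Hba-a1 at 2.43-fold lower (2.17 to 2.72) and the haem synthesis gene Alas2 at 1.97-fold (1.74 to 2.24). Of 38 genes of proteins secreted by hepatocytes 4 were lower and 0 higher, among them the complement genes C8a at 4.13-fold lower (3.91 to 4.36) and C9 at 3.68-fold (3.45 to 3.93). Of 18 sinusoidal endothelial markers none was 2-fold from the median gene, and their median was -0.45. Cytochrome P450 genes were higher in 13 of 26 cases and lower in 1, and of the sex-biased genes 15 were higher and 13 lower with G-CSF. Xist was 754-fold higher (323 to 2322), Ddx3y at least 225-fold lower and the male-biased Mup20 54.1-fold lower (47.4 to 62).

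Of 8845 genes 525 were at least 2-fold higher and 356 at least 2-fold lower with G-CSF, and the median gene of the list background stood at 0.14 on the log2 scale. Median-of-ratios scaling gave 349 higher and 467 lower, and leaving out the 50 most abundant genes 428 and 634. Medians relative to the median gene were 0.73 for lipogenesis, 0.66 for pericentral genes, 0.86 for cytochrome P450 genes and 2.06 for sex-biased genes, above every random list, and 0.49 for NRF2 targets (percentile 99.98) and 0.71 for neutrophil markers (99.66). They were -0.83 for red cell and platelet genes (0.05) and -0.18 for secreted proteins (1.65), with the endothelial list at percentile 0.03. In all, 7 of 39 lists stood apart above and 7 below. Those below also included bile duct markers, mitochondrially encoded genes and replication histone genes. The NRF2 and secreted protein lists lost their place at 50 RPM and in the transcript table, and the endothelial list at 50 RPM. The bile duct list lost its place with no filter on low values, and the mitochondrial and histone lists in the transcript table. Of the 20 most extreme genes 12 belonged to the sex lists. This counts listed genes only, so the other extremes cannot be taken as free of sex differences. Cyp2c69 and Serpina1e, in neither sex list, were among the most extreme genes in each comparison with the APAP library. Cyp2c69 was lower in the APAP library each time, like most listed female-biased genes, and Serpina1e higher, like the male-biased genes. Whether they are sex-biased was not tested.

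APAP plus exosomes against APAP plus G-CSF compares the treatments, in libraries that both had Xist and few or no Y-linked reads. With 1 RPM added to both sides, the acute phase genes Saa2 and Saa1 had the lowest ratios. Saa2 was 74.8-fold lower (59.8 to 94.8) with exosomes and Saa1 55.3-fold (47 to 65.5), at 19 RPM against 1051. Of 25 acute phase genes 11 were lower relative to the median gene and 2 higher, Orm2 being 9.96-fold lower (7.79 to 12.9) and the fibrinogen gene Fga 5.99-fold (5.88 to 6.09). Slc7a11 was 39-fold lower (31.1 to 49.6), the quinone reductase gene Nqo1 6.41-fold (5.04 to 8.28) and Gsta1 6.92-fold (6.2 to 7.74), with 8 of 26 NRF2 targets lower and 1 higher, the stress gene Osgin1 at 4.68-fold higher (4.51 to 4.85). Immediate early genes stood higher with exosomes in 24 of 26 cases and none was lower: Junb was 11.2-fold higher (10.04 to 12.5), Fos 9.997-fold (9.08 to 11), Ier2 9.53-fold (8.66 to 10.5) and Btg2 9.36-fold (8.62 to 10.2).

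Cytokine and chemokine genes were higher in 9 of 17 cases, Cxcl10 at 27.2-fold higher (23.3 to 31.9), Cxcl2 at 8.28-fold (7.15 to 9.62) and the NF-κB regulator gene Nfkbiz at 8.39-fold (7.61 to 9.27), and 15 of 28 interferon genes were higher, Ifit2 at 5.48-fold higher (4.19 to 7.23) and Isg15 at 3.08-fold (2.47 to 3.86). Cell type markers also stood higher relative to the median gene, which was itself at -0.64 on the log2 scale. Relative medians were 0.89 for monocyte and macrophage markers (percentile 99.99), 0.71 for Kupffer markers (99.83), 0.50 for sinusoidal endothelium (99.54) and 0.67 for stellate cell and matrix genes (99.8). On the deposited scale the summed RPM of monocyte and macrophage markers was 1287 with exosomes and 2227 with G-CSF. It was 1438 and 1890 for Kupffer markers, 798 and 896 for endothelium, and 1288 and 1200 for stellate and matrix genes. At 50 RPM these lists no longer stood apart, except Kupffer markers, which lost their place in the transcript table. The growth factor gene Hbegf was 22-fold higher (17.2 to 28.6). Lipogenesis genes were lower in 5 of 21 cases and higher in 1, with the carboxylase genes Acacb at 9.58-fold lower (8.04 to 11.5) and Acaca at 4.63-fold (3.98 to 5.41), and pericentral genes in 8 of 24, with Cyp2a5 at 7.18-fold lower (6.79 to 7.6) and Slc1a2 at 6.42-fold (5.15 to 8.09). The lipid droplet gene Plin4 was 21-fold lower (16.9 to 26.5), the metalloproteinase gene Mmp3 at least 57-fold and the immunoglobulin gene Ighm 28.8-fold (17.9 to 49.6). Clock genes went both ways, 7 of 18 higher and 3 lower, with the repressor gene Nfil3 at 4.17-fold higher (3.71 to 4.69). Red cell and platelet genes were higher in 6 of 6 cases, Hba-a1 at 6.79-fold higher (6.15 to 7.51), and neutrophil markers in 6 of 10, Retnlg at 7.33-fold higher (5.44 to 10.03), with 1 lower, Lcn2 at 3.96-fold lower (3.68 to 4.27). The mitochondrial transfer RNA gene mt-Tl2 was 13.2-fold higher (11.6 to 15), beside a Yam1 share of 13.2% against 1.79%.

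Of 8590 genes 375 were at least 2-fold higher and 2615 at least 2-fold lower with exosomes, and the median gene of the list background stood at -0.64 on the log2 scale. Median-of-ratios scaling gave 950 higher and 700 lower, a trimmed mean of log ratios 755 and 1015, and leaving out the 50 most abundant genes 742 and 1682. Relative medians were 2.33 for immediate early genes, 1.08 for cytokines, 1.07 for interferon genes and 3.15 for red cell and platelet genes, above every random list, and 1.66 for neutrophil markers (percentile 99.93) and 0.85 for clock genes (99.99). Acute phase genes at -0.63 and pericentral genes at -0.57 lay below every random list, NRF2 targets at -0.36 (percentile 0.2) and lipogenesis at -0.36 (0.72). In all, 19 of 39 lists stood apart above and 5 below. The NRF2 list lost its place at 50 RPM, and lipogenesis without the 50 most abundant genes and in the transcript table. None of the 20 most extreme genes belonged to the sex lists, but this comparison was not free of sex-linked differences. Ddx3y stood at 3.08 RPM with exosomes against 0 reads with G-CSF, and of 28 sex-biased genes 2 were higher and 6 lower relative to the median gene. Their list (percentile 15.82) stood apart under 6 of 8 alternatives, median-of-ratios scaling and a minimum of 50 RPM among them.

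**Figure D3:**
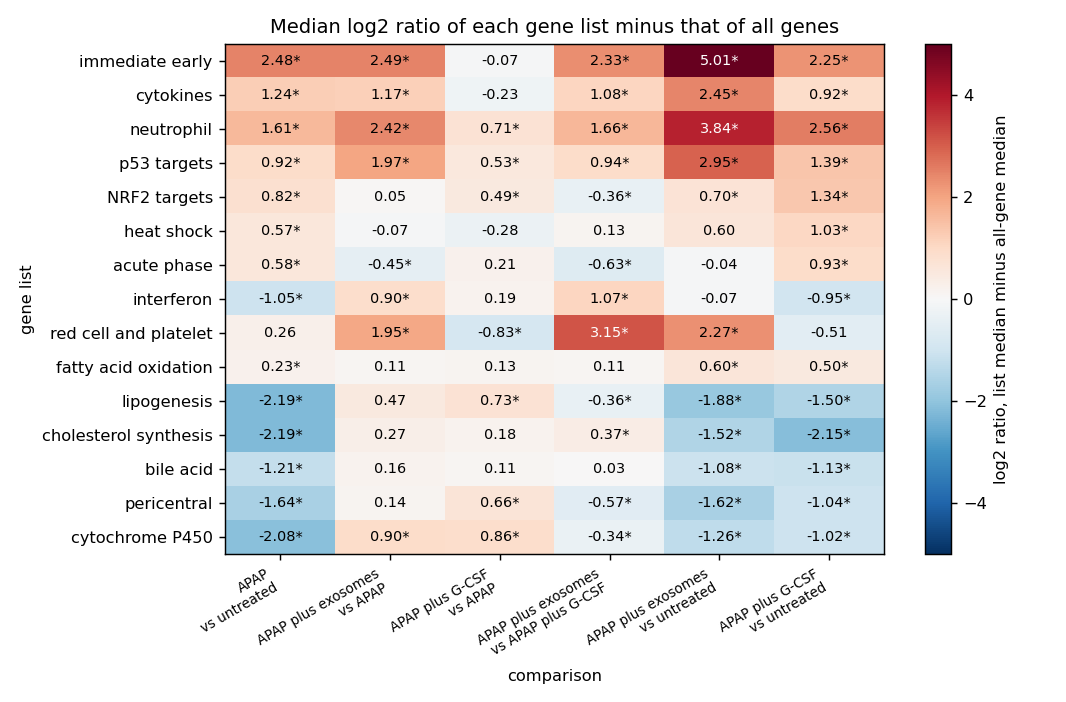
Median log2 ratio of the members of 15 gene lists minus the median of all genes, for the 6 comparisons (columns), with a star where the list lay outside the central 95% of 10000 random lists matched on expression. Immediate early genes reach 5.01 for APAP plus exosomes against untreated liver, and cholesterol synthesis lies between -2.19 and -1.52 for the 3 comparisons with untreated liver.

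Both treated libraries were also set against untreated liver. With exosomes all 26 of 26 immediate early genes were at least 2-fold higher relative to the median gene: the stress transcription factor gene Atf3 (chromosome 1, 191170296 to 191183333) was 255-fold higher (188 to 356), Maff 167-fold (117 to 246) and Fos 85.1-fold (63.4 to 117), Atf3 itself being outside that list. Cytokine genes were higher in 13 of 17 cases and lower in 1, with Cxcl2 at 479-fold higher (163 to 2325) and Cxcl10 at 97.9-fold (71.1 to 139). All 10 measured neutrophil markers were higher, S100a8 at 109.5-fold higher (49.9 to 299.9), and all 6 measured red cell and platelet genes, Hbb-bs at 7.48-fold higher (7.12 to 7.87). Of 32 listed neutrophil genes only these 10 reached 10 RPM in any liver library, and the 32 together held 20.3 RPM in untreated liver. Most could be measured only because a treated library was high, so the neutrophil count was partly set by the filter. Of 17 p53 targets 9 were higher, Gadd45a at 50.5-fold higher (40.6 to 63.5), and of 29 injury and regeneration genes 20 were higher and 3 lower, the growth factor gene Hbegf at 235-fold higher (100.3 to 726). Other cell type and RNA class lists stood apart too, with relative medians of 2.30 for bile duct markers (percentile 99.99), 0.61 for stellate cell and matrix genes (98.075), 0.70 for Kupffer markers (97.6) and 1.27 for structural RNAs (99.87). The bile duct list lost its place with no filter on low values, the stellate list under 2 alternatives, median-of-ratios scaling among them, the Kupffer list under 4 of 8 and the structural RNA list in the transcript table. The metal-binding protein gene Mt2 was 122-fold higher (94.8 to 161), and of 18 clock genes 8 were higher and 2 lower. Lipogenesis was lower in 16 of 21 cases, cholesterol synthesis in 19 of 25 and pericentral genes in 20 of 24, with Elovl6 at 20.3-fold lower (15.1 to 27.7), Idi1 at 15.7-fold (8.84 to 30.8) and Slc1a2 at 22.7-fold (18.3 to 28.4). Acute phase genes were split, 3 higher, such as Socs3 at 21.6-fold higher (17.6 to 26.9), and 3 lower, such as Crp at 4.03-fold lower (3.68 to 4.42), of 25.

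With G-CSF against untreated liver, Slc7a11 was 277-fold higher (168 to 496), Gsta1 99-fold (70.7 to 143) and Hmox1 48.9-fold (43.3 to 55.3), and 15 of 26 NRF2 targets were higher and none lower. Acute phase genes were higher in 12 of 25 cases and lower in 3, with Saa2 at 54.5-fold higher (46.3 to 64.5) and Saa1 at 48.4-fold (42.6 to 55.3). Heat shock genes were higher in 8 of 16 cases, the chaperone gene Hspb8 at 7.16-fold higher (6.78 to 7.56), and immediate early genes in 21 of 26, Klf6 at 18.8-fold higher (16.1 to 22.2). All 10 measured neutrophil markers were higher, S100a9 at 25.8-fold higher (14.2 to 52.1), a count that the filter on low values again partly set. Fatty acid oxidation and lipid droplet genes were higher in 12 of 36 cases and lower in 2, Cidec at 91.7-fold higher (67.5 to 128) and the kinase gene Pdk4 at 17.8-fold (15.4 to 20.7), and metal and iron genes in 6 of 15, Mt1 at 19.9-fold higher (17.7 to 22.4). Cholesterol synthesis was lower in 21 of 25 cases, Idi1 at 9.89-fold lower (6.9 to 14.6), lipogenesis in 14 of 21, Pnpla3 at 13.2-fold lower (8.004 to 23.1). Pericentral genes were lower in 12 of 24 cases, Cyp7a1 at 5.19-fold lower (4.56 to 5.92), and interferon genes in 13 of 28, Psmb9 at 7.27-fold lower (4.94 to 11). Nr0b2, a repressor of bile acid synthesis, was 54.5-fold lower (29.4 to 115).

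The exosome library had 985 genes at least 2-fold higher and 2286 lower than untreated liver of 8309, and the G-CSF library 1758 and 768 of 8808. The median gene of the list background stood at -0.38 with exosomes and 0.31 with G-CSF. Median-of-ratios scaling gave 1526 higher and 1582 lower for exosomes and 1007 and 1232 for G-CSF, a trimmed mean of log ratios 1389 and 1765 and 1169 and 1116, and leaving out the 50 most abundant genes 1572 and 2082 for exosomes. With exosomes 15 lists stood apart above and 7 below, and with G-CSF 14 and 12. Relative medians with exosomes were 5.01 for immediate early genes, 2.45 for cytokines, 3.84 for neutrophil markers, 2.27 for red cell and platelet genes, 2.95 for p53 targets, 1.99 for injury and regeneration, 0.97 for clock genes, -1.88 for lipogenesis, -1.52 for cholesterol synthesis and -1.62 for pericentral genes. With G-CSF they were 1.34 for NRF2 targets, 0.93 for acute phase genes, 1.03 for heat shock genes, 2.25 for immediate early genes, 2.56 for neutrophil markers, 0.50 for fatty acid oxidation, 0.60 for metal and iron genes, -2.15 for cholesterol synthesis, -1.50 for lipogenesis, -1.04 for pericentral genes and -0.95 for interferon genes. These lists lay outside the central 95% of random lists except acute phase genes with exosomes (median -0.04, percentile 32.41), which stood apart in the transcript table. With G-CSF the interferon list lost its place at 50 RPM and the metal and iron list with no filter on low values. Among 8117 genes tested in both comparisons with untreated liver, 650 were higher in both where independent lists would share 150.2, 618 were lower in both (216 for independent lists) and 47 were opposite. The log2 ratios correlated across genes at 0.75, where unchanged libraries simulated against the same untreated library gave 0.50, with a covariance of 0.90 against a simulated 0.0071. Among 8426 genes tested against APAP in both, 122 were higher in both (18.8 for independent lists), 184 lower in both (91.4) and 49 opposite, with a correlation of 0.48 against a simulated 0.54 and a covariance of 0.29 against 0.0079. Simulated unchanged libraries shared 0 calls. Genes are not independent replicates. The simulated values cover counting error in the shared library, and part of each excess may come from what was particular to the shared pool, which with 1 pool per group was not separable.

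For genes shifted by APAP, the level in the treated libraries was compared with both ends. Of the 1090 genes higher with APAP, 39.5% (36.6 to 42.5, exact binomial interval) lay nearer to untreated than to APAP in the exosome library and 17.2% (15.0 to 19.5) in the G-CSF library. Of the 694 genes lower with APAP, 19.9% (17.0 to 23.1) and 27.7% (24.4 to 31.2) lay nearer to untreated. Libraries simulated at the APAP level gave at most 0.144% by counting noise, and when the APAP reads were divided at random, so that different reads chose the genes and set their level, the mean was at most 0.694%. Without the sex lists the shares were 38.7% and 16% for higher genes and 18.7% and 26.2% for lower genes, with 1075 higher and 680 lower genes left. This took out listed genes only, so it could not show that sex played no part. The untreated, exosome and G-CSF libraries held Xist and the APAP library almost none. A sex difference alone could thus bring genes nearer to untreated, and it was not separable from treatment here. The simulated and the divided libraries cover counting noise only. The exact binomial intervals treat genes as independent, which they are not, and cover no difference between pools or scalings. Differences between pools of animals, which can also bring genes chosen as extreme in the APAP library nearer to untreated, were not measured. Among members of the gene lists that were shifted by APAP, with the lists named here picked after their values were seen, 9 of 11 acute phase genes lay nearer to untreated with exosomes and 1 with G-CSF, and 6 of 14 NRF2 targets with exosomes and 1 with G-CSF. For pericentral genes it was 1 of 16 with exosomes and 11 with G-CSF, for lipogenesis 2 and 8 of 18, for immediate early genes 0 and 2 of 23, and for neutrophil markers 0 and 0 of 4. Of 24 shifted sex-biased genes all lay nearer to untreated with G-CSF and 21 with exosomes. Median-of-ratios scaling put the shares of higher genes at 24.6% and 23.0% and those of lower genes at 29.1% and 18.1%, so which treatment had the larger share of lower genes turned with the scaling. A trimmed mean of log ratios put higher genes with exosomes at 25.3%.

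The small RNA libraries counted reads per microRNA hairpin. In APAP plus exosome liver, mir-122, the dominant microRNA of hepatocytes, took 23.4% of 1943448 reads on 1193 hairpins (exact binomial interval 23.4 to 23.5), with the red cell microRNA mir-451a at 6.45%, mir-29a at 2.21% and mir-22 at 2.19%. mir-451b, on the opposite strand of the mir-451a locus, was listed at 6.48%, but only 70 of its reads were forward and 125874 reverse, beside 125267 forward reads of mir-451a. In human serum exosomes, a pool of at least 10 donors, 254089 reads fell on 1881 hairpins, with mir-451a at 4.07%, mir-122 at 3.95% and mir-16-1 at 3.14%. There mir-451b (4.11%) had 10 forward and 10422 reverse reads, and mir-3591 (3.91%), opposite mir-122, had 843 forward and 9091 reverse reads. The liver list took 40.2% (40.1 to 40.3) in mouse liver and 10.97% (10.8 to 11.1) in human serum exosomes, the red cell list 15.3% (15.2 to 15.3) and 17.5% (17.3 to 17.6), the endothelial and stromal list 3.79% (3.76 to 3.81) and 1.55% (1.5 to 1.6), and the white cell list 1.02% (1.00 to 1.03) and 1.26% (1.22 to 1.31). The 10 most abundant hairpins took 48.7% and 27.2% of the reads. Organism, material and mapping differ, so these shares are set side by side and not tested. Shares include reads of both strands, so the red cell list holds mir-451a and mir-451b, and on forward reads only it took 10.4% in mouse liver and 19.4% in human serum exosomes. Hairpin mir-3591, opposite mir-122, was in no list, so the liver and red cell lists treat such pairs unequally in human serum exosomes. The liver list also holds let-7, mir-21 and mir-26a hairpins, and mir-122 made up 3.95 of its 10.97 percentage points there. The let-7, mir-16 and mir-486 copies share sequence, and how such reads were counted is not given in the sources used here. In human serum exosomes mir-16-1 and mir-16-2 had 7985 and 7981 reads. Counting a read at each copy, or dividing reads evenly between copies, would both give such near-equal counts. If reads were counted at each copy, the totals, shares and intervals count some reads more than once.

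**Figure D4:**
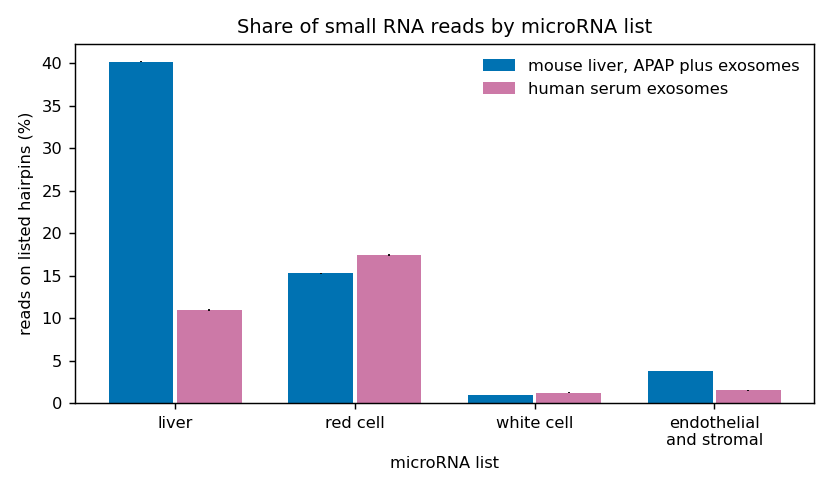
Share of small RNA reads (percent, axis from 0) on hairpins of 4 microRNA lists in the mouse liver library of APAP plus exosomes and in human serum exosomes, with exact 95% binomial intervals as black lines. The liver list takes 40.2% in mouse liver and 10.97% in human serum exosomes, and the red cell list 15.3% and 17.5%. The red cell list includes mir-451b, read almost wholly on its reverse strand, while mir-3591, opposite mir-122, is in no list.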

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

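All explanations weighed here were chosen for testing only after the result was seen. Reads on the reverse strand of microRNA hairpins were singled out because the strand of the reads, which the shares set side by side do not separate, held a signal above the limit that a count of 0 allows. These reads are part of those shares. They made up 16.1% of reads in the mouse liver small RNA library and 35.4% in human serum exosomes. Among the abundant hairpins, mir-451b, mir-126b and mir-142b in mouse and mir-451b and mir-3591 in human overlap another hairpin on the opposite strand, so a read from one member of such a pair appears as a reverse read of the other. These hairpins held 42.9% of the reverse reads in mouse liver and 21.7% in human serum exosomes, and the source of the other reverse reads was not tested.

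The library labelled APAP held Y-linked reads and almost no Xist. If its pool held male livers and the other pools female livers, sex-biased genes would lie on the male side in it, and 26 of 28 did against all 3 other libraries, so male liver in that pool is a candidate explanation that fits. A swap of the libraries labelled APAP and untreated would put the stress genes in the library labelled untreated, but the median log2 ratio of immediate early genes was 2.69 in the library labelled APAP, which speaks against that swap. Against untreated liver, the libraries with exosomes and with G-CSF, which also held Xist, differed the same way as APAP in immediate early genes (relative medians 2.48 with APAP, 5.01 with exosomes and 2.25 with G-CSF) and in cholesterol synthesis (-2.19, -1.52 and -2.15), so the sex difference of the APAP library is not needed for these. The exosome library held less Xist than untreated liver, however. Against untreated liver the sex-biased list stood apart below with exosomes and with G-CSF, under all 8 alternatives, so these comparisons were not free of differences in sex-biased genes. Where only the APAP library differs from the others, apart from the sex-linked genes themselves, sex and treatment were not separable with 1 library.

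More genes were lower than higher with exosomes than with APAP alone on the deposited scale (481 higher and 2164 lower). The excess depends on the scaling: median of ratios gave 997 higher and 888 lower (median log2 ratio -0.06), and a trimmed mean of log ratios 1016 and 819 (-0.03). Both scalings are built to bring typical genes near equality. A median near 0 thus follows largely by construction and cannot tell which scale is right. Abundant genes taking a larger share of the reads would remove the shift once left out, but the median log2 ratio was still -0.38 without the 50 most abundant genes, so they were not the whole cause. The ratio did not follow genomic span across genes, with a Spearman coefficient of -0.053 and span known for 94.4% of genes. Span includes introns and is not transcript length, so this could not decide on a bias by transcript length. Differences in library preparation and in total RNA per cell could each leave such a shift and were not tested.

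With exosomes acute phase genes stood lower and immediate early genes higher than with G-CSF. Less hepatocyte RNA cannot account for the size of the difference, as Alb was 1.33-fold lower while Saa1 was 55.3-fold lower. Collection at different times of day could not be told from other causes, as the mean log2 ratio of the positive clock genes minus that of the output genes was -0.97. Treatment, time since dosing and differences between the pooled animals may each explain the pattern and were not separable here.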

How the results depend on the processing

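No gene list that stood apart and no named gene at least 2-fold from equal turned its direction under any alternative, while the direction that held more genes did turn with the scaling in several comparisons. Gene lists kept their call in 1656 cases across lists, comparisons and alternatives, lost it in 63 and gained it in 57. Most losses came with the transcript table (28 lost, 17 gained), where genes, unit and summing all differ, and a minimum of 50 RPM (19 lost, 8 gained), which leaves fewer genes in each list. With no filter 9 calls were lost and 12 gained, without the 50 most abundant genes 3 and 8, under median-of-ratios scaling 2 and 3, under a trimmed mean of log ratios 1 and 2, with 5 RPM added 1 and 6, and with 0.1 RPM added 0 and 1. Among named genes below 2-fold, the log2 ratio of Csf3r between exosomes and APAP (-0.11) was 0.32 under median-of-ratios scaling, 0.33 under a trimmed mean of log ratios and 0.05 without the 50 most abundant genes. In the transcript table that of Dpp4 was -0.05 for APAP against untreated (0.31 as reported) and -0.03 for G-CSF against untreated (0.66), and that of Hbb-bt was 0.21 for G-CSF against APAP (-0.42). Ratios of named genes stayed within their counting interval in 971 cases and left it in 1159. The demand that the counting interval exclude 1 removed 0 genes. Leaving out replicates was not possible with 1 library per group, and no paired analysis was possible because each group has 1 library. Counting microRNAs only gave no value, as all listed features are microRNA hairpins. The exact binomial test, the sex lists left out and forward reads only were chosen after seeing the data. Fold, filter and binomial alternatives change by construction which genes pass. Median-of-ratios and trimmed mean scaling are built to bring typical genes toward equality, so a more even split can follow from the scaling itself. For the others the cause was not tested. Depth sets the smallest level: 3 reads are 0.385 RPM in the exosome library and 0.216 RPM in the G-CSF library.

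At 1.5-fold there were 2386 higher and 1304 lower for APAP against untreated, 904 higher and 4043 lower for exosomes against APAP, 1641 higher and 921 lower for G-CSF against APAP, 668 higher and 4692 lower for exosomes against G-CSF, 1590 higher and 3575 lower for exosomes against untreated and 3234 higher and 1450 lower for G-CSF against untreated. Of genes shifted by APAP, 51.3% of higher genes with exosomes and 16.6% of lower genes with exosomes then lay nearer to untreated. At 4-fold there were 205 higher and 167 lower for APAP against untreated, 135 higher and 245 lower for exosomes against APAP, 68 higher and 82 lower for G-CSF against APAP, 129 higher and 290 lower for exosomes against G-CSF, 344 higher and 470 lower for exosomes against untreated and 377 higher and 173 lower for G-CSF against untreated. Of genes shifted by APAP, 32.2% of higher genes with exosomes, 27.5% of lower genes with exosomes and 41.3% of lower genes with G-CSF then lay nearer to untreated. At a minimum of 50 RPM there were 394 higher and 435 lower for APAP against untreated, 262 higher and 614 lower for exosomes against APAP, 272 higher and 126 lower for G-CSF against APAP, 191 higher and 909 lower for exosomes against G-CSF, 433 higher and 919 lower for exosomes against untreated and 773 higher and 433 lower for G-CSF against untreated. The lists that stood apart then numbered 8 for G-CSF against APAP. By the exact binomial test there were 4077 higher and 2417 lower for APAP against untreated, 1473 higher and 5519 lower for exosomes against APAP, 3880 higher and 2122 lower for G-CSF against APAP, 1146 higher and 6241 lower for exosomes against G-CSF, 2238 higher and 4662 lower for exosomes against untreated and 4808 higher and 2440 lower for G-CSF against untreated. Under median-of-ratios scaling there were 997 higher and 888 lower for exosomes against APAP, 349 higher and 467 lower for G-CSF against APAP, 950 higher and 700 lower for exosomes against G-CSF, 1526 higher and 1582 lower for exosomes against untreated and 1007 higher and 1232 lower for G-CSF against untreated. Of genes shifted by APAP, 24.6% of higher genes with exosomes, 23% of higher genes with G-CSF, 29.1% of lower genes with exosomes and 18.1% of lower genes with G-CSF then lay nearer to untreated. With no filter on low values there were 2037 higher and 1005 lower for APAP against untreated, 855 higher and 3514 lower for exosomes against APAP, 839 higher and 750 lower for G-CSF against APAP, 774 higher and 3892 lower for exosomes against G-CSF and 1703 higher and 3433 lower for exosomes against untreated. With 5 RPM added there were 724 higher and 572 lower for APAP against untreated and 391 higher and 1420 lower for exosomes against APAP. In the transcript table there were 422 higher and 346 lower for APAP against untreated, 158 higher and 891 lower for exosomes against APAP, 267 higher and 323 lower for G-CSF against APAP, 255 higher and 1157 lower for exosomes against G-CSF, 229 higher and 962 lower for exosomes against untreated and 503 higher and 397 lower for G-CSF against untreated. The lists that stood apart then numbered 7 for exosomes against APAP, 9 for G-CSF against APAP and 10 for exosomes against G-CSF. Under a trimmed mean of log ratios there were 667 higher and 1000 lower for APAP against untreated, 1016 higher and 819 lower for exosomes against APAP, 755 higher and 1015 lower for exosomes against G-CSF and 1169 higher and 1116 lower for G-CSF against untreated. Of genes shifted by APAP, 25.3% of higher genes with exosomes, 26.9% of lower genes with exosomes and 23.3% of lower genes with G-CSF then lay nearer to untreated. Without the 50 most abundant genes there were 764 higher and 2062 lower for exosomes against APAP, 428 higher and 634 lower for G-CSF against APAP, 742 higher and 1682 lower for exosomes against G-CSF and 1572 higher and 2082 lower for exosomes against untreated. Of genes shifted by APAP, 23.4% of higher genes with G-CSF and 24.8% of lower genes with exosomes then lay nearer to untreated.

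On forward reads only, the shares in mouse liver and in human serum exosomes were 51.5% and 31.1% for the 10 most abundant microRNAs, 47.7% and 16.1% for the liver list, 10.4% and 19.4% for the red cell list, 1.07% and 1.63% for the white cell list and 4.11% and 1.94% for the endothelial and stromal list. With copies summed, the shares in mouse liver and in human serum exosomes were 49% and 29% for the 10 most abundant microRNAs. Without the most abundant hairpin, the shares in mouse liver and in human serum exosomes were 34.4% and 24.9% for the 10 most abundant microRNAs, 21.9% and 11.4% for the liver list, 19.98% and 13.9% for the red cell list, 1.33% and 1.31% for the white cell list and 4.94% and 1.61% for the endothelial and stromal list.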

Other observations

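Tests of gene lists in this part were read only after their results were seen. Ribosomal protein genes, which encode the protein part of cytosolic ribosomes, stood higher than the median gene against untreated liver in all 3 treated libraries. Their median log2 ratio relative to the median gene was 0.63 with APAP, 1.06 with APAP plus exosomes and 0.56 with APAP plus G-CSF, for 45 genes, at percentiles 100, 100 and 99.99 of random lists. Conjugation enzymes, which attach glucuronide, sulfate or glutathione to drugs, stood lower in the same 3 comparisons, with medians of -1.15, -0.63 and -1.04 at percentiles 0, 0.39 and 0. With exosomes this list no longer stood apart at a minimum of 50 RPM. Cell death genes stood higher in all 3, with medians of 0.58, 0.84 and 0.84 at percentiles 99.88, 99.76 and 99.99.

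Structural and abundant nuclear RNAs, such as small nuclear and vault RNAs, stood higher with exosomes in 11 of 13 cases against APAP and 10 against G-CSF, with medians of 1.35 and 1.35 relative to the median gene. In the transcript table this list did not stand apart in either comparison. Histone genes used in DNA replication, whose transcripts lack a poly(A) tail, were lower with G-CSF than in untreated liver in 5 of 6 cases, with a median of -1.64 (percentile 0.02). Mitochondrial transfer RNAs took 2.06% of reads in untreated liver, 1.09% with APAP, 4.50% with exosomes and 1.15% with G-CSF.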
